A study of Mus musculus with 12 samples.

How the data were processed

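RNA was sequenced from 12 libraries of CD31-sorted cells of mouse cerebral cortex, 3 per group. The deposited table, made by the authors, holds read counts per gene as whole numbers for 54532 genes, and its unit is the count. Per the submitters' processing notes, reads were trimmed with fastp 0.19.7, aligned to mm10 with HISAT2 2.0.5 and counted with featureCounts, and DESeq2 1.20.0 was used for their own tests, which are not analysed here. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Of the gene identifiers, 54409 (99.8%) are in GENCODE vM21, and 53499 have the same coordinates there. Where several identifiers share a symbol (203 identifiers), a protein-coding one was preferred in gene lists, and then the most abundant one.

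Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14297, scaled with TMM factors (0.731 to 1.41) and fitted in 1 quasi-likelihood model of all 12 libraries with robust estimation and 1 coefficient per group. Each ASD group was compared with Control, the ASD groups with each other and their mean with Control, and 1 test asked for any difference among the 4 groups. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that comparison, and "higher", "lower", "rose" and "fell" refer to such genes, and of a list to its camera call. Fold changes are on the log2 scale, group values are means ± SD over n = 3 libraries of CPM, and CPM of named genes are TMM-scaled while marker sums use the total counts of a library.

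The comparisons, the alternatives, 46 gene lists with 1089 genes (34 of functions and 12 of cell types) and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and 44 lists had at least 5 tested members. None of the lists called by camera in any of the 7 comparisons was called with an estimated correlation. Summed marker CPM were compared with exact two-sided permutation tests in Python 3.11.15 (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9.

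Named genes are protein coding and were taken by this rule. For each comparison with Control they are the 8 higher and the 8 lower with the smallest adjusted p among those that passed with a fold of at least 1.5, a mean of at least 1 CPM and no overlap between the groups' libraries. For comparisons between durations and for the mean they are 5 in each direction, and where none passed, the 3 in each direction with the smallest unadjusted p. Genes always named included Cdkn1a, Cdkn2a, Trp53, Lmnb1, Pecam1, Cldn5, Ocln, Tjp1, Cdh5, Per1, Dbp, Arntl and Fkbp5. Added were up to 4 passing members of each list called by camera, or with at least 3 passing members, against Control, and the most abundant member of each cell type list in Control as a level. The text prints part of the genes that the rule names. Slc2a1, Map3k6 and Txnip were chosen after their values were seen.

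Totals of 6525056 to 8267760 counts put 3 counts, the limit that a count of 0 allows, at 0.363 to 0.460 CPM, and such limits and the binomial intervals cover counting error only. On simulated counts with the same group sizes and spread, 200 genes were changed by 1.5-, 2- or 4-fold. Of those changed 4-fold, edgeR recovered 62.1 to 75.8%, and of those changed 2-fold 8.96 to 20.9%. Its false calls were 0 to 8.20% of its calls, those of DESeq2 14.9 to 25.5% and those of limma voom 0 to 5.56%. No simulated library was given a wider spread than the others.

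The alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the 2 compared groups alone, each library left out in turn, a block for the replicate numbers, a fold of at least 2 and a cell type level as covariate. Settings added later are named where they are used. Other splits of the libraries were counted, 10 for each pair of groups and 100 for the whole set.

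No library was left out of the main comparisons. Exon positions were compared between genes. Because the strand setting is unknown, levels are uncertain for genes that share many exon bases with another gene, among them Rpl35 (66.2%) and Nos3 (32.3%).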

Results

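The libraries hold poly(A) RNA of cells sorted from the cerebral cortex of male C57BL/6J mice, an inbred laboratory strain, with magnetic beads against CD31. CD31, the product of Pecam1, is an adhesion molecule carried by endothelial cells and also by platelets and some leukocytes. There were 4 groups of 3 libraries: undisturbed mice (Control) and mice kept awake on a slowly turning rod for 6, 12 or 24 h (ASD6h, ASD12h and ASD24h, where ASD stands for acute sleep deprivation). Per the labels, deprivation began at 8 in the morning, so it ended at clock hours 14, 20 and 8, and duration and time of day changed together. The hour at which Control mice were collected is not given in the sources used here. The title names senescence and function of brain endothelial cells as the subject. The files hold 6525056 to 8267760 counts per library, from 7053453 to 7308207 in Control, 6525056 to 7800298 in ASD6h, 7056234 to 8267760 in ASD12h and 7491514 to 7905111 in ASD24h. After a filter on low counts, 14297 genes were tested. The labels do not say whether a library is 1 mouse or a pool of mice, so the p-values measure only the spread between these samples.

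Transcripts of other brain cells made up much of the sorted RNA in every group. In Control, 29 genes of endothelial identity summed to 9041 ± 4778 CPM (mean ± SD, n = 3), where CPM are the counts of a gene scaled to the total of its library. The sums were 22148 ± 2460.2 CPM for 15 oligodendrocyte genes, 7814 ± 3049.6 CPM for 18 neuronal genes and 6016 ± 545 CPM for 16 astrocyte genes. In TMM-scaled CPM, as for all named genes, the most abundant marker of each list reached 12242 ± 1284 CPM for Mbp (myelin), 4351 ± 2501 CPM for Camk2a (a neuronal kinase) and 2099 ± 249 CPM for Slc1a2 (an astrocyte glutamate transporter) in Control. The endothelial sum was 2728 ± 420.1, 2929 ± 749.7 and 1922 ± 609 CPM in ASD6h, ASD12h and ASD24h. In each group it was below all Control libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give, adjusted p = 0.279 over 39 tests). Scaled with TMM, as in the gene tests, it overlapped with Control at 12 h (exact permutation p = 0.2). Pericyte genes summed to 1054 ± 679 CPM in Control and to 302 ± 98.0, 359 ± 50.4 and 267 ± 49.6 CPM in the ASD groups, without overlap at 6 h and 24 h. Astrocyte genes were without overlap lower at 12 h (3326 ± 430.0 CPM) and 24 h (4831 ± 492 CPM), while neuronal sums overlapped with Control in each group. On the TMM scale pericyte sums overlapped at 6 h and astrocyte sums at 24 h (0.986 times Control), and neuronal sums were higher without overlap at 12 h (2.02 times) and 24 h (1.97 times). Oligodendrocyte sums, which overlapped on deposited totals, were then higher without overlap in each group (1.58, 1.37 and 1.32 times). Chance gives such a non-overlap in 10% of comparisons of 3 with 3 libraries.

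**Figure D1:**
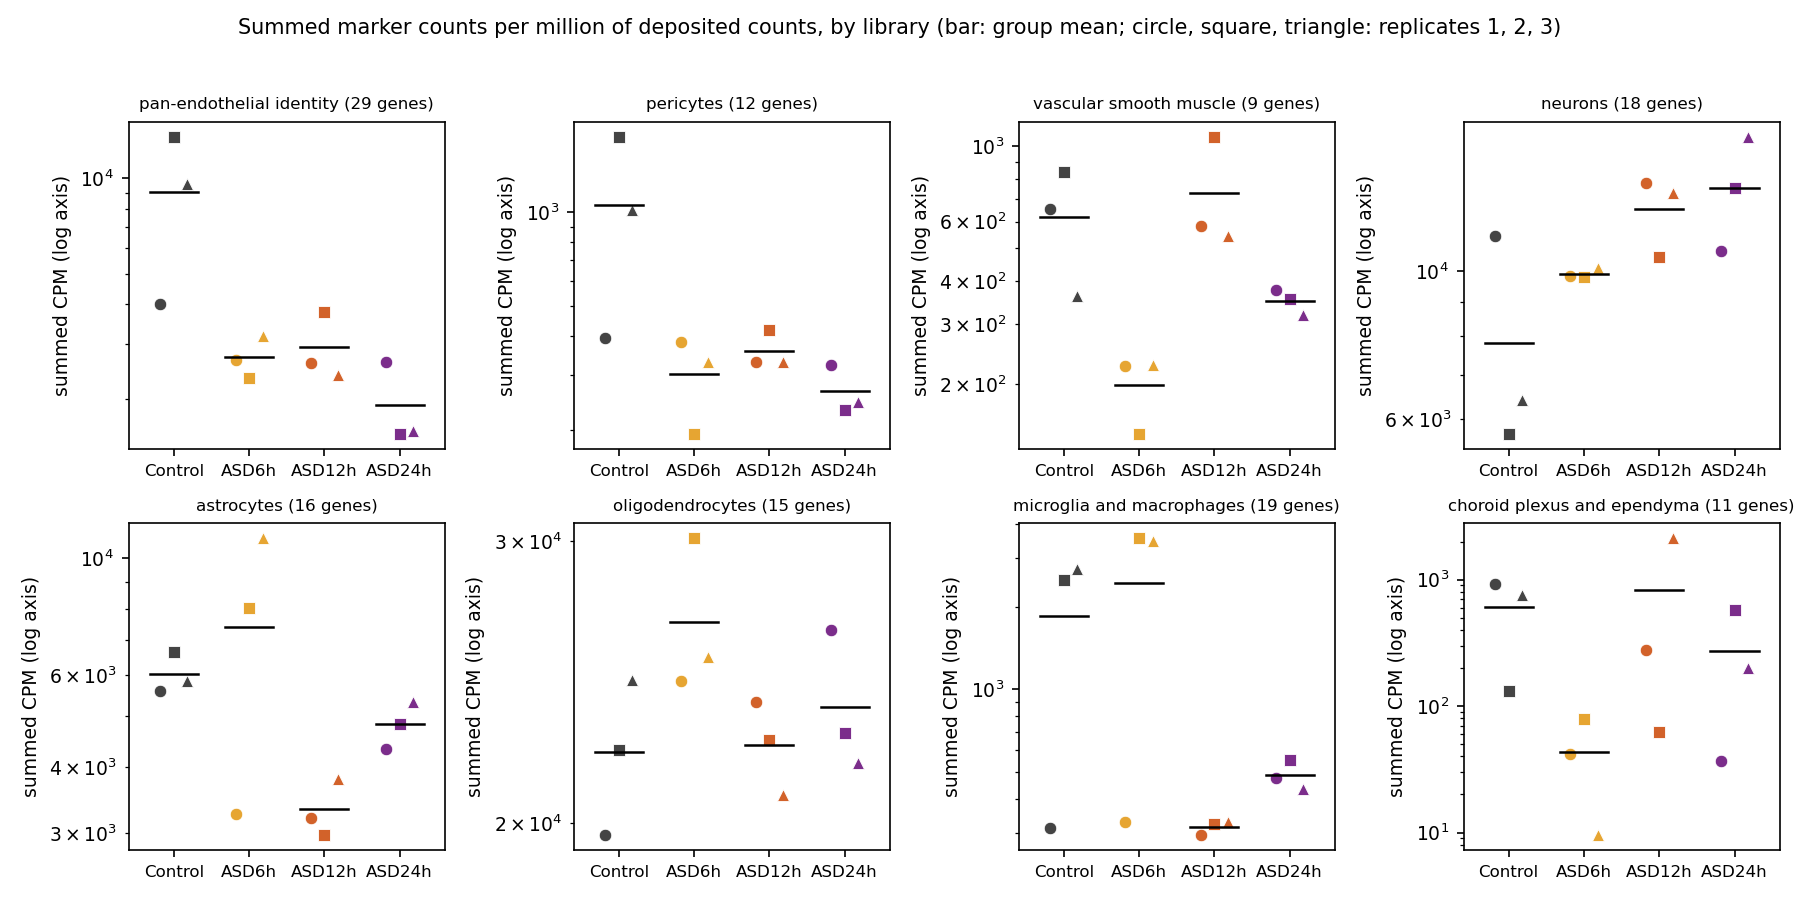
Summed CPM of marker genes (log axis) for the cell types named above each panel, with 1 point per library and a bar at the mean of each group of 3. The endothelial sums of the 9 ASD libraries lie between 1555 and 3786 CPM, below Control library 1 at 4008 CPM and the other Control libraries at 9599 and 13516 CPM.

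Microglial genes summed to 2493 to 3547 CPM in Control libraries 2 and 3 and ASD6h libraries 2 and 3 and to 295 to 552 CPM in all others, Control library 1 (313 CPM) and ASD6h library 1 (329 CPM) included. Genes of lymphocytes and neutrophils split the libraries in the same way, at 52.0 to 82.0 and 0.958 to 10.9 CPM. The labels name no batch. Without both first libraries, ASD6h libraries 2 and 3 differed from Control libraries 2 and 3 in 4272 genes. Control library 1 alone has a low microglial sum in its group, so ASD12h and ASD24h cannot be compared with Control among libraries of like sums.

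Control library 1 differed from the other 11 libraries. It held 13640 genes with a count, against 18128 to 20092 in the others, although its total of 7308207 counts was within their range. Of the genes with a mean of at least 50 counts in the other libraries, 103 had none in it, against at most 3 in any other library. Its neuronal genes summed to 11311 CPM, above the 5706 and 6425 CPM of Control libraries 2 and 3, and its pericyte genes to 393 CPM. Mitochondrially encoded RNA made up 34.0%, 17.4% and 24.3% of the counts of Control libraries 1 to 3 (95% Wilson interval of the first 34.01 to 34.08%), and 24.9 to 46.4% in the ASD libraries. It was kept in all comparisons, and the number of genes that passed without it is given for each.

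The comparison of ASD6h with Control asks what 6 h of deprivation changed in the sorted material. Genes of endothelial identity, of the blood-brain barrier and of the vessel wall fell, among them the junction gene Cldn5, the nitric oxide synthase gene Nos3 and the elastin gene Eln. Sgk1, a kinase gene that glucocorticoids induce, rose, as did Cdkn1a, which encodes the cell cycle inhibitor p21, and genes of ribosomal proteins and of the respiratory chain. Of the 14297 genes tested, 231 were higher and 370 lower, 601 in all. The count was 4199, 26 and 198 without Control library 1, 2 or 3 and 280, 1 and 91 without ASD6h library 1, 2 or 3. Of 87 calls of genes chosen to be named, 1, 70 and 34 ended without Control library 1, 2 or 3 and 37, 86 and 56 without ASD6h library 1, 2 or 3. The 1 gene that passed without ASD6h library 2 was Sgk1, and in the lists named here the most genes passed without Control library 1. All levels are relative to other RNA of the same library. Marker sums use its total counts, and fold changes and CPM of named genes use TMM-scaled totals. The choice matters: the endothelial sum at 6 h was at log2 -1.73 against Control on total counts and at -1.26 with TMM. Scaled to the endothelial identity genes instead, the median log2 change of all genes moved to 1.17, 0.97 and 1.76 at 6, 12 and 24 h, and 8, 10 and 18 genes were lower.

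Eln, which encodes the elastic fibre protein of artery walls (chromosome 5, 134702593 to 134747323, mm10), fell from 104 ± 25.9 to 22.1 ± 2.95 CPM (log2 -2.24, SE 0.26, adjusted p = 0.00646). Aoc3, an adhesion amine oxidase of vessels, fell from 16.4 ± 4.36 to 2.77 ± 0.251 CPM (log2 -2.56, SE 0.31, adjusted p = 0.00683). The riboflavin transporter gene Slc52a3 (log2 -1.90), the epoxide hydrolase gene Ephx1 (-1.67), the natriuretic peptide receptor gene Npr1 (-1.89) and the matrix gene Tinagl1 (-1.91) were among the other genes with the smallest p. All 29 endothelial identity genes had lower estimates, with 0 higher, 11 lower and 18 not passing (0 to 29 lower with 1 library left out), or 0 and 29 adjusted over the list alone (median log2 -1.26, camera adjusted p = 7.39e-22, or 0.247 with an estimated correlation). No list called by camera, which assumes a correlation of 0.01 between genes, passed in any of the 7 comparisons when the correlation was estimated (smallest adjusted p = 0.0708). Nos3 fell by 1.72 and the receptor gene Tie1 by 1.67 on the log2 scale, while Pecam1 itself did not pass (log2 -1.17, SE 0.36, adjusted p = 0.0809, and adjusted p = 0.0102 without Control library 1). The 25 blood-brain barrier transporter genes, which carry nutrients such as amino acids and lipids into the brain, gave 0 higher, 8 lower and 17 not passing (0 to 21 lower with 1 library left out), or 0 and 21 adjusted over the list alone (camera adjusted p = 3.08e-15). Slc38a5 was at log2 -1.85. The 20 basement membrane genes gave 0 higher, 10 lower and 10 not passing (0 to 20 lower with 1 library left out), or 0 and 18 adjusted over the list alone (camera adjusted p = 7.66e-15). The collagen chaperone gene Serpinh1 was at log2 -1.74. In the junction list, Cldn5, whose claudin seals the barrier (chromosome 16, 18776847 to 18778262), fell from 607 ± 165 to 225 ± 83.4 CPM (log2 -1.43, SE 0.33, adjusted p = 0.0352). Ocln (adjusted p = 0.0680), Tjp1 (0.213) and Cdh5 (0.0629) did not pass with all libraries and passed without Control library 1 (adjusted p = 0.00224, 0.00606 and 0.00159). The call of Cldn5 was lost without Control library 2 (adjusted p = 0.115) or 3 (0.0827) and without ASD6h library 2 (0.163) or 3 (0.0979).

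Sgk1 (chromosome 10, 21882184 to 21999903) rose from 11.4 ± 4.17 to 54.9 ± 14.3 CPM (log2 2.27, SE 0.26, adjusted p = 0.00646) and passed whichever library was left out. Ksr2, a scaffold of the MAP kinase pathway, rose by log2 1.49. The potassium channel gene Kcnk2 (log2 1.07), the postsynaptic scaffold gene Dlgap2 (1.43), the cofactor gene Lmo3 (1.27) and the progesterone receptor gene Pgr (1.52) were higher too. The 78 cytosolic ribosomal protein genes gave 10 higher, 0 lower and 68 not passing (0 to 34 higher with 1 library left out), or 26 and 0 adjusted over the list alone (camera adjusted p = 7.66e-15). Rpl38 was at log2 1.40 and Rps21 at 1.05. The 76 nuclear genes of oxidative phosphorylation gave 7 higher, 0 lower and 69 not passing (0 to 23 higher with 1 library left out), or 14 and 0 adjusted over the list alone (camera adjusted p = 1.92e-08). Cox7c was at log2 1.03. The 13 mitochondrially encoded mRNAs gave 3 higher, 0 lower and 10 not passing (0 to 9 higher with 1 library left out), or 5 and 0 adjusted over the list alone (camera adjusted p = 3.67e-06). mt-Co3 was at log2 2.51. Mural, meningeal and choroid plexus genes were lower as lists. The 12 pericyte genes gave 0 higher, 2 lower and 10 not passing (0 to 10 lower with 1 library left out), or 0 and 8 adjusted over the list alone (camera adjusted p = 2.87e-06). Vtn was at log2 -1.58. The 8 fibroblast genes gave 0 higher, 4 lower and 4 not passing (0 to 6 lower with 1 library left out), or 0 and 6 adjusted over the list alone (camera adjusted p = 3.58e-05). The collagen gene Col1a2 was at log2 -1.91. The 9 smooth muscle genes gave 0 higher, 2 lower and 7 not passing (0 to 2 lower with 1 library left out), or 0 and 7 adjusted over the list alone (camera adjusted p = 3.20e-05). Myl9 was at log2 -1.30. No neuronal gene passed, although the 18 genes had a median log2 of 0.57 (camera adjusted p = 0.000762). Without Control library 1, 16 of them passed, and without Control library 2 camera did not call the list (adjusted p = 0.107).

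The comparison of ASD12h with Control asks the same of 12 h of deprivation. Ribosomal protein genes were the list with the most members past the test, and all that passed rose. Barrier transporter and capillary genes, such as the transferrin receptor gene Tfrc and the lipid transporter gene Mfsd2a, fell, and so did Icam1, which encodes a leukocyte adhesion molecule of endothelium. Neuronal genes rose. In all 2016 genes passed, 1129 higher and 887 lower. The count was 6374, 252 and 654 without Control library 1, 2 or 3, and 60, 1009 and 379 without ASD12h library 1, 2 or 3. Of 111 calls of genes chosen to be named, 1, 71 and 54 ended without Control library 1, 2 or 3 and 86, 37 and 70 without ASD12h library 1, 2 or 3. In the lists named here the fewest genes passed without ASD12h library 1 and the most without Control library 1.

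Rps27, a gene of the small ribosomal subunit (chromosome 3, 90212522 to 90213651), rose from 42.2 ± 9.36 to 172 ± 16.5 CPM (log2 2.03, SE 0.22, adjusted p = 0.00232). Of the 78 cytosolic ribosomal protein genes there were 66 higher, 0 lower and 12 not passing (6 to 72 higher with 1 library left out), or 75 and 0 adjusted over the list alone (median log2 0.81, camera adjusted p = 1.29e-32, or 0.452 with an estimated correlation). Genes of this family have near-identical copies in the genome, and the handling of reads that map to several places is not given in the sources used here. Their levels are therefore uncertain, as is that of Rpl35 (log2 1.66), which shares 66.2% of its exon bases with another gene. The 76 nuclear oxidative phosphorylation genes gave 40 higher, 0 lower and 36 not passing (3 to 53 higher with 1 library left out), or 48 and 0 adjusted over the list alone (camera adjusted p = 1.27e-16). Cox7c was at log2 1.42 and Ndufa3 at 1.26. Ksr2 (chromosome 5, 117414000 to 117775003) rose from 10.9 ± 0.429 to 41.5 ± 6.78 CPM (log2 1.93, SE 0.19, adjusted p = 0.00189). Sgk1 rose to 47.6 ± 4.34 CPM (log2 2.07, SE 0.25, adjusted p = 0.00232). The ribosome assembly gene Zfp622 (log2 1.57), the linker histone gene H1fx (1.65) and Pgr (1.87) were higher as well. Fkbp5, a chaperone gene induced through the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), was called at 12 h only, at 47.0 ± 9.25 CPM against 21.5 ± 8.08 CPM (log2 1.13, SE 0.28, adjusted p = 0.0255). That call was lost without Control library 2 (adjusted p = 0.0970) and without ASD12h library 1 (0.116) or 3 (0.0811), and Fkbp5 did not pass at 6 h (log2 0.38) or 24 h (-0.16). Its differences between 12 h and 6 h (adjusted p = 0.264) and between 24 h and 12 h (0.219) did not pass either. The 30 glucocorticoid-induced genes as a list gave 3 higher, 3 lower and 24 not passing (1 to 3 higher and 0 to 13 lower with 1 library left out), or 3 and 4 adjusted over the list alone (camera adjusted p = 0.780).

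Icam1 (chromosome 9, 21015985 to 21028817) fell from 32.5 ± 6.02 to 10.1 ± 0.442 CPM (log2 -1.69, SE 0.21, adjusted p = 0.00260). The matrix gene Adamtsl2 (log2 -2.84), the glutamine transporter gene Slc38a3 (-1.56), the cytoskeletal regulator gene Cdc42ep1 (-1.46) and the kinase gene Map3k3 (-1.21) were among the others with the smallest p. The 25 barrier transporter genes gave 0 higher, 15 lower and 10 not passing (1 to 24 lower with 1 library left out), or 0 and 20 adjusted over the list alone (camera adjusted p = 1.68e-12). Tfrc, which carries transferrin-bound iron, fell from 294 ± 118 to 57.9 ± 4.33 CPM (log2 -2.34, SE 0.45, adjusted p = 0.0116), a call that ended without ASD12h library 1 (adjusted p = 0.0711). The 12 capillary genes gave 0 higher, 10 lower and 2 not passing (0 to 11 lower with 1 library left out), or 0 and 10 adjusted over the list alone (camera adjusted p = 3.26e-08). Mfsd2a was at log2 -1.80 and the matrix gene Hmcn1 at -2.73. The endothelial identity list gave 0 higher, 16 lower and 13 not passing (0 to 27 lower with 1 library left out), or 0 and 26 adjusted over the list alone (median log2 -1.12, camera adjusted p = 2.08e-13, or 0.452 with an estimated correlation). Kdr, the main VEGF receptor gene, was at log2 -1.49. Cldn5 (log2 -0.83, SE 0.32, adjusted p = 0.0956) and Pecam1 (log2 -0.75, SE 0.35, adjusted p = 0.155) did not pass with all libraries and passed without Control library 1 (adjusted p = 0.0141 and 0.0363). Neuronal genes gave 8 higher, 0 lower and 10 not passing (0 to 18 higher with 1 library left out), or 12 and 0 adjusted over the list alone (camera adjusted p = 8.76e-08). The glutamate transporter gene Slc17a7 was at log2 1.40. The 19 microglial genes gave 0 higher, 5 lower and 14 not passing (0 to 14 lower with 1 library left out), or 0 and 10 adjusted over the list alone (camera adjusted p = 0.000151). P2ry12 was at log2 -2.64 and Tmem119 at -2.59. The microglial sums of 295 to 328 CPM at 12 h enclose that of Control library 1 (313 CPM), and the lower level rests on Control libraries 2 and 3 (2493 and 2743 CPM). The smooth muscle list gave 2 higher, 0 lower and 7 not passing (0 to 3 higher with 1 library left out), or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0104). Tpm2 was at log2 1.17. Camera did not call that list without Control library 3 (adjusted p = 0.102) or ASD12h library 2 (0.117).

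The comparison of ASD24h with Control asks the same of 24 h of deprivation. Every endothelial identity gene on the fixed list passed and was lower, and so were the CD31 gene Pecam1 and the junction genes Cldn5, Ocln, Tjp1 and Cdh5. Antigen presentation, interferon and adhesion genes also fell, as did microglial genes as a list and Per1 and Dbp of the clock, while the clock activator gene Arntl (Bmal1) rose. Neuronal genes rose, and so did the calcium channel subunit gene Cacna2d1. In all 3072 genes passed, 1389 higher and 1683 lower. The count was 6695, 1442 and 1829 without Control library 1, 2 or 3 and 2717, 1174 and 1375 without ASD24h library 1, 2 or 3. Of 143 calls of genes chosen to be named, 1, 27 and 19 ended without Control library 1, 2 or 3 and 10, 34 and 23 without ASD24h library 1, 2 or 3. In most lists named here the fewest genes passed without ASD24h library 2 and the most without Control library 1.

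Pecam1 (chromosome 11, 106654217 to 106750628) fell from 385 ± 128 to 119 ± 41.9 CPM (log2 -1.69, SE 0.36, adjusted p = 0.00757). Cldn5 fell from 607 ± 165 to 222 ± 43.2 CPM (log2 -1.45, SE 0.33, adjusted p = 0.00969), a call that ended without ASD24h library 2 (adjusted p = 0.0503). Ocln (log2 -1.88), Cdh5 (-1.79) and Tjp1 (-1.46) passed too. The call of Tjp1 ended without Control library 2 (adjusted p = 0.0614) and without ASD24h library 2 (0.0752) or 3 (0.0746). The 29 endothelial identity genes gave 0 higher, 29 lower and 0 not passing (21 to 29 lower with 1 library left out), or 0 and 29 adjusted over the list alone (median log2 -1.79, camera adjusted p = 2.06e-24, or 0.242 with an estimated correlation). The 25 barrier transporter genes gave 0 higher, 24 lower and 1 not passing (11 to 25 lower with 1 library left out), or 0 and 25 adjusted over the list alone (median -1.83, camera adjusted p = 2.85e-19). Slc7a5, the large neutral amino acid transporter gene (chromosome 8, 121881150 to 121907694), fell from 834 ± 476 to 118 ± 23.3 CPM (log2 -2.83, SE 0.43, adjusted p = 0.00192). Ephx1 (chromosome 1, 180976210 to 181020904) fell from 89.1 ± 23.7 to 16.0 ± 1.17 CPM (log2 -2.48, SE 0.22, adjusted p = 0.000548). Icam1 (log2 -2.23), the tetraspanin gene Tspan4 (-3.00), the sulfhydryl oxidase gene Qsox1 (-2.21) and Eln (-2.35) were lower as well. The 25 NF-kB target and adhesion genes gave 1 higher, 10 lower and 14 not passing (1 to 2 higher and 5 to 18 lower with 1 library left out), or 1 and 15 adjusted over the list alone (camera adjusted p = 5.71e-06). The inhibitor gene Nfkbia was at log2 -2.20 and the chemokine gene Cx3cl1, also a neuronal gene, higher at 1.13. The 41 interferon response genes gave 0 higher, 9 lower and 32 not passing (2 to 30 lower with 1 library left out), or 0 and 14 adjusted over the list alone (camera adjusted p = 2.12e-06). Gbp5 was at log2 -1.85 and Ifitm3 at -1.31. The MHC list gave 0 higher, 6 lower and 15 not passing (2 to 10 lower with 1 library left out), or 0 and 8 adjusted over the list alone (camera adjusted p = 0.0208). Tap2 was at log2 -1.62. Without Control library 2 camera did not call this list (adjusted p = 0.106). Scaled to the endothelial identity genes, where most genes turned higher by construction, these lists were not lower. The adhesion, interferon and MHC lists then had medians of 0.69, 0.81 and 1.05, with 5, 11 and 8 members higher and 0 lower. The 19 microglial genes gave 0 higher, 2 lower and 17 not passing (0 to 12 lower with 1 library left out), or 0 and 0 adjusted over the list alone (camera adjusted p = 0.0172). That call ended without Control library 2 (adjusted p = 0.0536) or 3 (0.184). The microglial sums were 433 to 552 CPM at 24 h, against 313, 2493 and 2743 CPM in Control libraries 1 to 3. Fatty acid oxidation genes gave 0 higher, 5 lower and 14 not passing (3 to 9 lower with 1 library left out), or 0 and 9 adjusted over the list alone (camera adjusted p = 0.00279). The carnitine transferase gene Cpt1a was at log2 -1.73. Scaled to the endothelial identity genes, the microglial and fatty acid lists were not lower either. Their medians were 0.72 and 1.25, with 2 and 11 members higher and 0 lower.

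Arntl (chromosome 7, 113207465 to 113314126) rose from 5.08 ± 3.20 to 16.3 ± 2.08 CPM (log2 1.70, SE 0.49, adjusted p = 0.0282). Per1 (log2 -1.41, SE 0.31, adjusted p = 0.00863), Dbp (log2 -1.50, SE 0.37, adjusted p = 0.0153) and Nr1d2 (log2 -1.37) fell. The 20 clock genes gave 2 higher, 5 lower and 13 not passing (0 to 6 higher and 3 to 8 lower with 1 library left out), or 3 and 7 adjusted over the list alone (camera adjusted p = 0.387). Camera asks for 1 common direction, and Arntl and Dbp are expected in opposite phase, so it cannot decide on a shift of the clock. The call of Arntl was lost without Control library 2 (adjusted p = 0.0948) or 3 (0.0932) and without ASD24h library 1 (0.0511), 2 (0.0948) or 3 (0.0615), and that of Dbp without ASD24h library 1 (0.0523) or 2 (0.0581). Cacna2d1 (chromosome 5, 15934691 to 16374511) rose from 9.58 ± 0.796 to 44.3 ± 3.75 CPM (log2 2.21, SE 0.20, adjusted p = 0.000548). Ksr2 (log2 1.81), the inositol transporter gene Slc2a13 (2.10) and the synaptic adhesion gene Cadm2 (1.68) were higher. Neuronal genes gave 14 higher, 0 lower and 4 not passing (2 to 18 higher with 1 library left out), or 16 and 0 adjusted over the list alone (median log2 1.18, camera adjusted p = 3.51e-08). Syt1 was at log2 1.58. The 30 immediate early genes gave 4 higher, 9 lower and 17 not passing (2 to 7 higher and 2 to 13 lower with 1 library left out), or 5 and 11 adjusted over the list alone (camera adjusted p = 0.171). Among them were the neuronal gene Arc at log2 1.81, Nr4a3 at 1.51 and Jun at -1.21. Sgk1 was at 23.8 ± 1.43 CPM (log2 1.07, SE 0.25, adjusted p = 0.0118). The 30 glucocorticoid-induced genes gave 2 higher, 14 lower and 14 not passing (1 to 2 higher and 7 to 19 lower with 1 library left out), or 2 and 15 adjusted over the list alone (camera adjusted p = 0.000161). Cebpd was at log2 -2.36. Scaled to the endothelial identity genes, where most genes turned higher by construction, the glucocorticoid list had a median of 0.87 (14 higher, 0 lower). Its direction therefore depends on the scaling. Ribosomal protein genes gave 27 higher, 0 lower and 51 not passing (9 to 40 higher with 1 library left out), or 34 and 0 adjusted over the list alone (camera adjusted p = 1.73e-10). Nuclear oxidative phosphorylation genes gave 30 higher, 0 lower and 46 not passing (13 to 46 higher with 1 library left out), or 37 and 0 adjusted over the list alone (camera adjusted p = 5.68e-10).

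**Figure D2:**
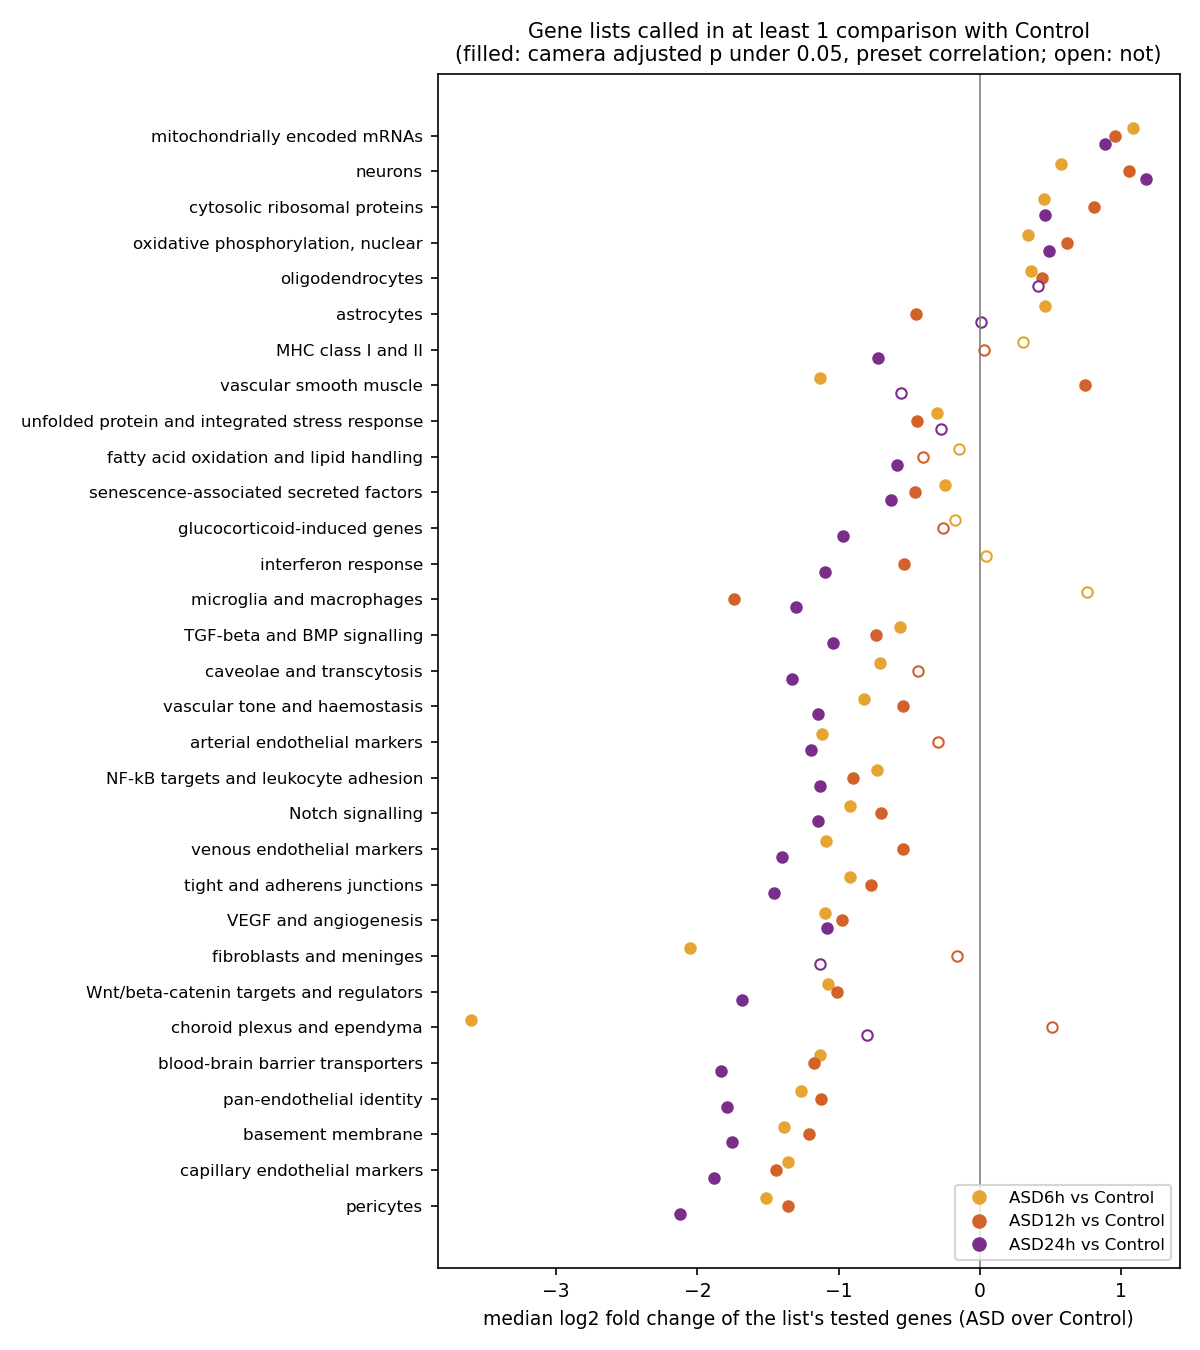
Median log2 fold change of each fixed gene list that camera called in at least 1 of the comparisons of ASD6h, ASD12h and ASD24h with Control. Lists called in none of them are not drawn. The endothelial identity list lies at -1.26, -1.12 and -1.79 and the ribosomal protein list at 0.45, 0.81 and 0.46.

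Senescence genes are the title's subject, and the fixed lists held genes of cell cycle arrest, p53 targets and secreted factors. Cdkn1a (chromosome 17, 29090976 to 29100727) rose from 9.65 ± 2.19 CPM in Control to 26.6 ± 7.97 at 6 h (log2 1.46, SE 0.34, adjusted p = 0.0365), 26.3 ± 10.1 at 12 h (log2 1.45, SE 0.34, adjusted p = 0.0204) and 22.2 ± 7.82 CPM at 24 h (log2 1.21, SE 0.34, adjusted p = 0.0251). Its calls ended without Control library 2 (adjusted p = 0.134, 0.0859 and 0.0929) or 3 (0.0864, 0.0605 and 0.0661). They also ended without ASD6h library 1, 2 or 3 (0.0953, 0.128 and 0.0624), ASD12h library 1 or 2 (0.0758 and 0.0650) and ASD24h library 2 or 3 (0.0550 and 0.112). Cdkn2a, which encodes p16, had 10 counts over the 12 libraries, at most 6 in 1 library, and was not tested. Trp53 (adjusted p = 0.697, 0.222 and 0.354) and Lmnb1 (0.242, 0.402 and 0.348) did not pass with all libraries. Without Control library 1, Trp53 was lower at 6 h (log2 -0.70, adjusted p = 0.0266), 12 h (-1.14, 0.000913) and 24 h (-0.95, 0.00247). At 6 h the 17 arrest genes gave 1 higher, 0 lower and 16 not passing (0 to 1 higher and 0 to 5 lower with 1 library left out), or 1 and 1 adjusted over the list alone. At 12 h they gave 2 higher, 2 lower and 13 not passing (0 to 2 higher and 0 to 6 lower with 1 library left out), or 2 and 2 adjusted over the list alone. At 24 h they gave 2 higher, 4 lower and 11 not passing (0 to 2 higher and 2 to 6 lower with 1 library left out), or 2 and 4 adjusted over the list alone. Camera did not call the list (adjusted p = 0.273, 0.462 and 0.156). Camera asks for 1 common direction, while the list holds cell cycle inhibitors such as Cdkn1a beside genes such as E2f1, Ezh2 and Lmnb1. These need not move together, so the list result cannot decide for or against arrest. E2f1 was higher at 12 h (log2 1.08), while Glb1, the gene of the galactosidase used to stain senescent cells, was lower at 12 h (-0.78) and 24 h (-1.22). The call of E2f1 and that of Glb1 at 12 h ended without Control library 2 (adjusted p = 0.125 and 0.119) or 3 (0.0972 and 0.103) and without any 1 of the ASD12h libraries (0.0542 to 0.177). The 25 p53 targets were not called either (camera adjusted p = 0.135, 0.225 and 0.0936, and 0.0171 at 6 h without ASD6h library 1), with Phlda3 higher at 12 h (1.21) and Fas lower at 24 h (-2.58). The 76 secreted factor genes were lower as a list at 24 h (camera adjusted p = 0.00191, or 0.242 with an estimated correlation, and 0.0128 without Control library 1). The camera calls at 6 h (adjusted p = 0.0490) and 12 h (0.0304) ended without Control library 1 (0.0842 and 0.0802) or 3 (0.114 and 0.0536), and that at 6 h also without ASD6h library 3 (0.0859). At 24 h they gave 4 higher, 19 lower and 53 not passing (1 to 12 higher and 10 to 29 lower with 1 library left out), or 5 and 20 adjusted over the list alone. Igfbp6 was higher (log2 1.31), and Icam1, which is also on the adhesion list, had the smallest p among those that fell. Scaling to the endothelial identity genes turned most genes higher by construction. On that scale the secreted factors had a median of 1.11 at 24 h (38 higher, 0 lower). The arrest genes had 1.46 (14 higher, 0 lower) and the p53 targets 1.38 (17 higher, 0 lower). The direction of the secreted factor list therefore depends on the scaling.

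**Figure D3:**
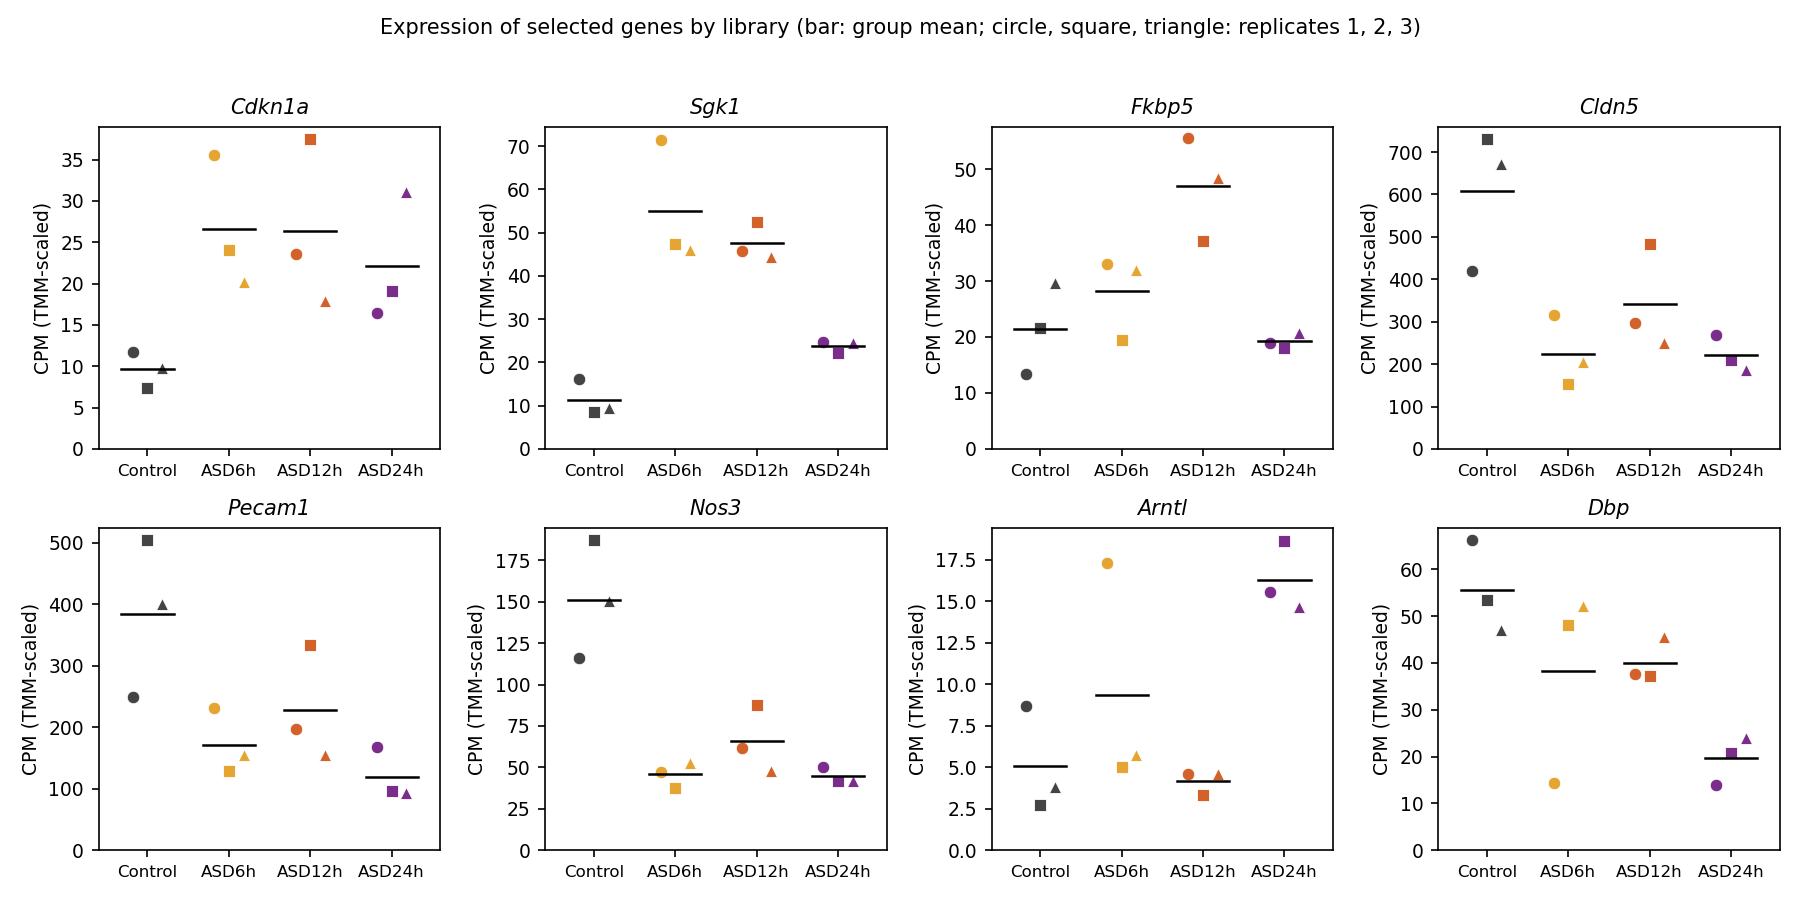
TMM-scaled CPM (linear axis) of Cdkn1a, Sgk1, Fkbp5, Cldn5, Pecam1, Nos3, Arntl and Dbp, with 1 point per library and a bar at each group's mean. Cdkn1a is at 11.8 CPM in Control library 1 and at 16.4 CPM or more in the 9 ASD libraries.

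The comparisons between durations ask which genes differ between 6, 12 and 24 h, and each also spans a different time of day. In edgeR 1, 0 and 0 genes passed, so the differences between lists given here rest on camera at its preset correlation. Aoc3 (chromosome 11, 101330605 to 101341938), which smooth muscle also expresses, was higher at 12 h (18.2 ± 6.48 CPM) than at 6 h (2.77 ± 0.251 CPM; log2 2.71, SE 0.31, adjusted p = 0.0157). It was the 1 gene that passed, while 1944 had an unadjusted p under 0.05. DESeq2 called 503 genes and limma 4523. The call of Aoc3 ended without ASD6h library 2 (adjusted p = 0.252) or 3 (0.18) and ASD12h library 1 (0.0671) or 2 (0.0580). The count was 981 without Control library 1, which is in neither group but enters the shared estimate of spread, and 410 without ASD6h library 1. Smooth muscle genes had a median log2 of 2.13 between 12 and 6 h (camera adjusted p = 8.00e-20, or 0.0897 with an estimated correlation), and fibroblast genes 1.70 (camera adjusted p = 1.04e-07, or 0.0708 with an estimated correlation). Choroid plexus genes had a median of 4.28 (camera adjusted p = 5.75e-08), or 2.07 without ASD12h library 3. Their sums were 279, 62.2 and 2129 CPM at 12 h and 41.8, 79.6 and 9.50 CPM at 6 h, and so overlapped. Microglial genes had a median of -2.62 (camera adjusted p = 6.65e-15), with ASD6h library 1 at the level of ASD12h (329 against 295 to 328 CPM). None of the 9 smooth muscle genes passed over all genes, and 9 did when adjusted over the list alone.

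Between ASD24h and ASD12h, edgeR called 0 genes, with 1116 at an unadjusted p under 0.05, and DESeq2 called 125 and limma 2240. Between ASD24h and ASD6h edgeR also called 0, with 1709 at an unadjusted p under 0.05, and DESeq2 called 294 and limma 6693. The genes with the smallest p, none of which passed, were Pnisr (log2 0.95), Zranb2 (0.87) and Zfc3h1 (1.03), genes of RNA processing, higher at 24 h than at 12 h. Those lower were Ephx1 (log2 -1.58), Ehd4 (-1.27) and Qsox1 (-1.36), and adjusted p was 0.105 to 0.219 over the 6 genes. Against 6 h they were Col6a1 (log2 4.42), Eml5 (1.95) and Cacna2d1 (1.28), higher, and Fyb (log2 -2.67), Bmf (-2.05) and Map3k3 (-0.93), lower (adjusted p = 0.0728 to 0.182). Without Control library 1 the counts were 233 and 1009, and without ASD6h library 1 the comparison with 6 h gave 201. The named genes of both comparisons passed without Control library 1, and those of the comparison with 6 h also without ASD6h library 1. Among the 233 genes, chosen after their values were seen, were the glucose transporter gene Slc2a1 (log2 -1.92, adjusted p = 0.000515), Map3k6 (-2.62) and Txnip (-1.63), lower at 24 h than at 12 h. The endothelial identity list had a median log2 of -0.75 between 24 and 12 h (camera adjusted p = 4.13e-14), smooth muscle genes -1.36 (camera adjusted p = 2.21e-13) and glucocorticoid-induced genes -0.57 (camera adjusted p = 8.38e-13). Between 24 and 6 h, interferon genes had a median of -1.07 (camera adjusted p = 1.37e-16) and microglial genes -2.17 (camera adjusted p = 4.75e-10). The microglial difference rests on ASD6h libraries 2 and 3 (3547 and 3460 CPM), since ASD6h library 1 (329 CPM) lay below ASD24h (433 to 552 CPM).

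The mean of the 3 ASD groups against Control asks which genes changed on average after deprivation. All endothelial identity genes fell, as did Icam1 and Eln, and Ksr2, Rps27 and the channel genes Kcnk2 and Cacna2d1 rose. The genes with the smallest p were Ksr2 (log2 1.74, SE 0.16, adjusted p = 0.000393), Rps27 (log2 1.75), Kcnk2 (1.18), Tmem28 (1.27) and Cacna2d1 (1.56) among those higher. Those lower were Icam1 (log2 -1.72, SE 0.16, adjusted p = 0.000393), Slc52a3 (log2 -1.73), Ephx1 (-1.68), Eln (-1.85) and Cdc42ep1 (-1.56). In all 3436 genes passed, 1527 higher and 1909 lower. The count was 6937, 1145 and 1794 without Control library 1, 2 or 3. A test for any difference among the 4 groups called 2130 genes. It called 6802, 456 and 754 without Control library 1, 2 or 3, 983 without ASD12h library 1 and 642 and 877 without ASD24h library 2 or 3. The endothelial identity list gave 0 higher, 29 lower and 0 not passing, or 0 and 29 adjusted over the list alone (camera adjusted p = 7.94e-25, or 0.203 with an estimated correlation).

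Many genes were called in the same direction after more than 1 duration, and 356 in all 3 comparisons (169 higher and 187 lower). Between 6 h and 12 h, 177 genes were shared among those higher and 191 among those lower, where independent lists would share 18.2 and 22.96. For 6 h and 24 h the shared counts were 191 and 331 (22.4 and 43.6 if independent), for 12 h and 24 h 785 and 667 (110 and 104), and 0 genes went in opposite directions. The comparisons use the same Control libraries, which alone gives their estimates a covariance. The covariance of log2 fold changes over all genes was 0.378, 0.499 and 0.689 for these pairs, above the 0.116, 0.115 and 0.116 of simulated sets without any group difference by 0.261, 0.384 and 0.573. With 3 Control libraries the controls cannot be split between comparisons, so part of the excess may come from the shared controls. The 356 shared genes were 3317, 12 and 114 without Control library 1, 2 or 3. They were not counted with an ASD library left out. Without ASD6h library 2, 1 gene passed at 6 h, and without ASD12h library 1, 60 passed at 12 h. The shared genes could not exceed these counts there.

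**Figure D4:**
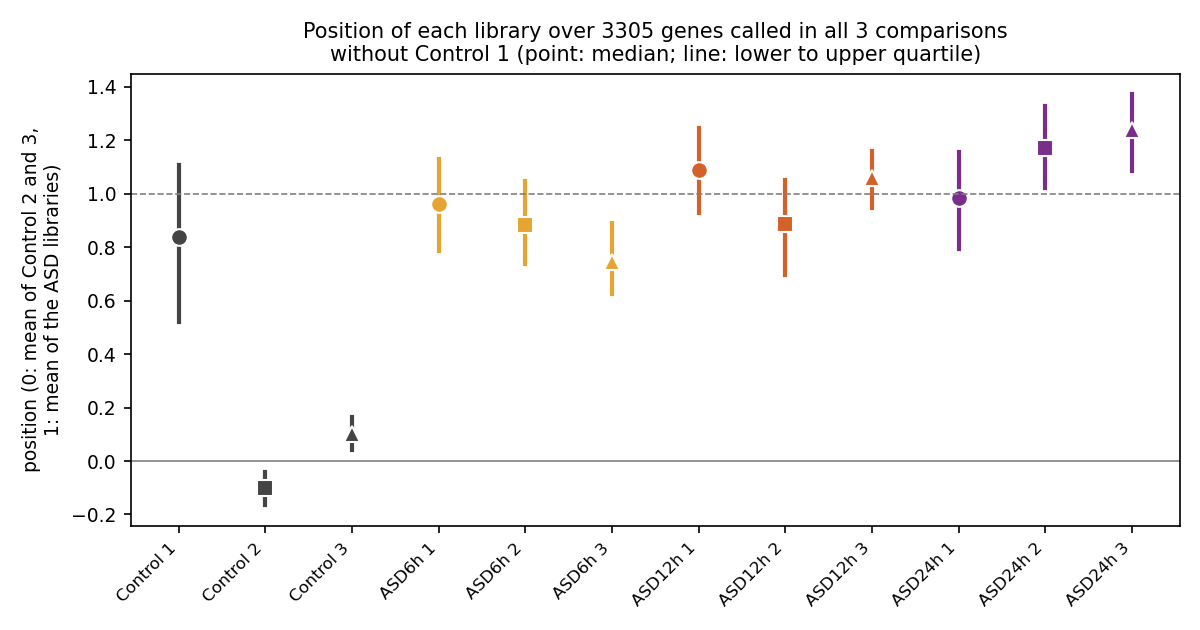
Position of each library between the mean of Control libraries 2 and 3 (0) and the mean of the ASD groups (1), as median and quartiles over 3305 genes, those of the 3317 called in all 3 comparisons without Control library 1 that were also tested with all libraries. These genes were chosen from the other 11 libraries, so those libraries lie near 0 and 1 by construction; Control library 1 lies at 0.84.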

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

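The comparisons between durations in this part were planned, and no test in it was chosen after its result was seen. Each result here stood out because 2 durations of deprivation differed in a test of the difference itself. Aoc3, the gene of an adhesion amine oxidase of endothelium and smooth muscle, had a log2 fold change of 2.71 (SE 0.31, edgeR adjusted p = 0.0157) in ASD12h against ASD6h. It was at 18.2 ± 6.48 CPM at 12 h, 2.77 ± 0.251 CPM at 6 h and 16.4 ± 4.36 CPM in Control, and higher in all 3 ASD12h libraries than in any ASD6h library. The call ended without ASD6h library 2 (adjusted p = 0.252) or 3 (0.18) and without ASD12h library 1 (0.0671) or 2 (0.0580).

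Camera called 14 gene lists between ASD12h and ASD6h, 9 higher and 5 lower, 29 between ASD24h and ASD12h, 5 higher and 24 lower, and 23 between ASD24h and ASD6h, 7 higher and 16 lower. With an estimated correlation camera called 0 of 44 in each of these comparisons. Fry called 2, 0 and 0. Of its calls, smooth muscle genes had a median log2 fold change of 2.13 in ASD12h against ASD6h (fry adjusted p = 0.0249, camera adjusted p = 0.0897 with an estimated correlation), and fibroblast genes 1.70 (fry adjusted p = 0.0116, camera adjusted p = 0.0708 with an estimated correlation).

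The smooth muscle genes summed to 198 ± 48.3 CPM at 6 h, 729.8 ± 291 CPM at 12 h, 351 ± 29.7 CPM at 24 h and 618 ± 240.0 CPM in Control. The fibroblast genes summed to 74.6 ± 19.98, 249.5 ± 61.5, 138 ± 24.6 and 186 ± 29.0 CPM. A sort for CD31 is meant to remove both cell types. Whether more of their RNA was carried through the sort at 12 h or their genes changed in the vessel wall was not tested, since the libraries hold no count of cells.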

How the results depend on the processing

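The mitochondrial, pericyte and endothelial settings and those that leave out both first libraries were chosen after the data were seen. The main counts were 601, 2016 and 3072 genes called for ASD6h vs Control, ASD12h vs Control and ASD24h vs Control, 1, 0 and 0 for ASD12h vs ASD6h, ASD24h vs ASD12h and ASD24h vs ASD6h, 3436 for the mean of ASD groups vs Control, 2130 for any difference among the 4 groups and 356 in the overlap of calls. Under RLE factors, upper-quartile factors and a filter of 1 CPM in 3 libraries each of these counts and those of lists stayed within 1.5 times, and the median log2 change over all genes moved by less than 0.1. So did the counts of genes without mitochondrially encoded genes. TMM trims a few abundant genes in any case. Of 390 values of named genes, 2 lost their call under RLE factors, 6 under upper-quartile factors, 12 without a filter, 59 with a replicate block and 173 with the neuronal covariate, besides the 6 that changed sign, and 18 gained one with DESeq2. Calls were lost by 240 of 378 values with only the groups compared, 168 of 377 without Control library 2 and 87 of 115 without ASD6h library 2.

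Leaving out 1 library at a time gave 1 to 4199 genes for ASD6h vs Control, 60 to 6374 for ASD12h vs Control, 1174 to 6695 for ASD24h vs Control, 0 to 981 for ASD12h vs ASD6h, 0 to 233 for ASD24h vs ASD12h, 0 to 1009 for ASD24h vs ASD6h, 1145 to 6937 for the mean and 456 to 6802 for any difference. The overlap was counted only with a Control library left out, and gave 12 to 3317. Without ASD6h library 2 it could hold at most the 1 gene called for ASD6h vs Control. The highest values came without Control library 1, whose voom weight was 0.057. A group left with 2 libraries is assumed to vary like the others. Lists called moved within 1.5 times.

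For ASD6h, ASD12h and ASD24h vs Control, ASD12h vs ASD6h, ASD24h vs ASD12h, ASD24h vs ASD6h, the mean, any difference and the overlap, in that order, limma voom called 7854, 8335, 10058, 4523, 2240, 6693, 9778, 11583 and 5323 genes, and leaving out the first libraries of both Control and ASD6h gave 4272, 7036, 7286, 2397, 523, 2323, 7382, 7877 and 3147. DESeq2 called 1689, 3381, 4121, 503, 125, 294, 4534, 4191 and 1033, and no filter gave 1571, 3215, 3817, 763, 248, 751, 4328, 4114 and 986. Fitting only the compared groups gave 0, 0, 807, 543, 283 and 308 for the pairs of groups and 0 for the overlap, where the zeros for 6 h and 12 h had 2042 and 3635 genes at an unadjusted p under 0.05. The fewer libraries leave fewer degrees of freedom in every pair. The pairs of ASD groups, which lack Control library 1, still gave more genes than in the main fit (1, 0 and 0). Fewer degrees of freedom do not by themselves lower the count. The main fit shares 1 estimate of spread per gene over all groups, so its calls at 6 h and 12 h assume that Control varies like the ASD groups. The voom weight of 0.057 for Control library 1 goes against that for this library. A fold of at least 2 left 1216 at 12 h and 1585 for the mean, by construction. The replicate numbers do not pair the libraries. A block for them gave 210 at 6 h, 0 for ASD12h vs ASD6h (1702 at an unadjusted p under 0.05), 1397 for any difference and 144 for the overlap. For the changes with limma voom, DESeq2 and no filter the cause was not tested.

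With the level of neuronal genes as covariate the counts were 1754, 834, 1301, 169, 213, 2 and 1824 for the comparisons up to the mean. With it 6 genes covered by the naming rule changed sign and lost their call (log2 0.0061 to 0.49), among them Pdgfb (0.0061) and Tapbp (0.0750) at 12 h and Abcc9 (0.17), H2-D1 (0.19) and P2ry12 (0.0837) at 24 h. With pericyte genes they were 1246 at 6 h, 1625 at 24 h, 544, 29 and 13 between durations, 2217 for the mean and 623 for the overlap. With the endothelial identity genes they were 7, 0, 0 against Control, 252 for ASD12h vs ASD6h, 0 for the mean, 52 for any difference and 0 for the overlap, with 2862, 2593 and 2837 genes at an unadjusted p under 0.05 for the zeros at 12 h, 24 h and the mean. This level lies far lower in each ASD group than in Control, so the covariate removes much of the group difference.

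Scaled to the endothelial identity genes, the median log2 change of all genes moved to 1.17, 0.97 and 1.76, so most genes turned higher by construction. The counts were 6171, 4002 and 10682 (overlap 3283), with 8, 10 and 18 genes lower, and 11193, 9169 and 12170 (overlap 8609) without Control library 1.

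Of the lists, camera with an estimated correlation called 0 in each of the 7 comparisons, and 0 in the comparisons with Control and of the mean without Control library 1. The main counts were 26, 24, 25, 14, 29, 23 and 25. Fry, which does not compare a list with other genes, called 11 at 6 h, 2 at 12 h, 2 for ASD12h vs ASD6h and 0 for the others between durations, and 22 at 24 h and 21 for the mean. The estimated correlations, such as 0.856 for endothelial identity genes at 6 h, far exceed the preset 0.01. Depth limits Cdkn2a, with 10 counts in all.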

Other observations

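In this part the tests of a lower endothelial share, of mitochondrial genes, of fixed proportions among other cells and of few starting molecules were chosen after the results were seen. So were the pericyte and endothelial levels as covariates, the scaling to endothelial genes and the endothelial sum of Control library 1. The tests of daily phase and of a mislabelled library, the neuronal covariate and the splits were planned.

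Endothelial genes were lower in each ASD group, and genes of other cells differed too. The tables argue against a lower endothelial share with the other cell types in fixed proportion, since the ratio of neuronal to astrocyte marker sums was 2.81 times that of Control at 12 h (3.74 ± 0.433 against 1.33 ± 0.616), without overlap at 12 h and 24 h. At 6 h the ratio was 1.30 times that of Control and overlapped with it, so it cannot decide there. Other sums argue against fixed proportions at 6 h. Pericyte, fibroblast and choroid plexus sums were 0.287, 0.402 and 0.0719 times Control. They and smooth muscle sums lay below all Control libraries. Neuronal, astrocyte and oligodendrocyte sums were 1.27, 1.23 and 1.21 times and overlapped. On the TMM scale choroid plexus sums were lower and oligodendrocyte sums higher without overlap, while pericyte, fibroblast and smooth muscle sums overlapped. A few mitochondrial genes taking the counts are argued against by the endothelial sum over the counts without them, not scaled by TMM, whose log2 ratio to Control was at most -1.36 (at 12 h). The highest ASD library was at 4981 CPM at 6 h and 4349 CPM at 24 h, but at 12 h it was at 6076 CPM and so level with Control library 1 (6077 CPM). For a lower share of endothelial RNA as such, the 63 genes of the barrier, capillary, arterial and venous lists as a pool are consistent with it, their medians within 0.14 (log2) of the endothelial identity median in each comparison. Taken alone, arterial genes lay 0.66 and 0.77 above the identity genes at 12 h and 24 h and venous genes 0.59 at 12 h (0.89, 0.63 and 0.50 without Control library 1). An equal lowering of genes expressed in endothelium alone does not give this. Whether other cells in the sorted material express the arterial and venous genes was not tested. A lower share therefore stays open, as the whole or a part of the pattern. RNA of other cells carried through the sort, which should remove them, cannot be told apart from the groups for the genes called against Control: the pericyte level as covariate ended 62.8% of 5689 calls (50.6%, 47.4% and 75.4% at 6, 12 and 24 h), their median log2 size going from 1.19 (SE 0.28) to 0.82 (SE 0.30), and 56.6% of that level's variance lay between groups. The planned neuronal level ended 77.6% of them, 86.0% at 12 h and 84.8% at 24 h but 13.3% at 6 h. Their median log2 size went to 0.68 in all and from 1.25 to 0.98 at 6 h. Most calls at 6 h stood, but this level (mean log2 CPM) was 7.52 in Control library 1, within the 6.95 to 7.54 of ASD6h. Control libraries 2 and 3 were at 5.75 and 6.30, so the neuronal level cannot decide at 6 h. The endothelial identity level as covariate ended 5687 of the 5689 calls, 599 of 601 at 6 h, with a median log2 size of 0.61 after. It lies far lower in each ASD group than in Control, so it cannot decide either. The pericyte level was used because neuronal sums overlapped between groups, a choice that turns with the scaling: on the TMM scale neuronal sums did not overlap with Control at 12 h and 24 h, and pericyte sums did at 6 h and 12 h. A lowering of endothelial genes within the cells stays open as a biological explanation and was not tested.

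Control library 1 stood apart from the other libraries. Few starting molecules would give genes at 0 counts whose mean elsewhere was at least 50, and it had 103, against at most 3 in any other library. Genes with 1 to 4 counts go the same way, at 370 against 3836 to 5053 in the other Control and the ASD libraries. A lower share of endothelial RNA is consistent with an endothelial sum that was 0.347 of the mean of the other Control libraries. A mislabelled sleep-deprived sample is consistent with its median position of 0.84 (quartiles 0.52 to 1.11) between the other Controls (0) and the ASD groups (1), while Control libraries 2 and 3, held out in the same way, lay at -0.20 over 12 genes and 0.24 over 114 genes. Other values go against mislabelling. Its Cdkn1a (11.8 CPM), a gene fixed beforehand, and Sgk1 (16.2 CPM), which the naming rule took for its difference, were below all ASD libraries. On the second principal component (29.5% of variance) it lay at -78.8, beside Control libraries 2 and 3 (-68.2 and -49.9), and the ASD libraries at -8.52 to 46.1. On the larger first component (35.9% of variance) it lay at -122, and Control libraries 2 and 3 at 63.1 and 52.98. The ASD libraries lay between, at -19.3 to 35.8, so that axis sets it apart from the other Control and the ASD libraries. The values against mislabelling are 2 genes and the second axis, which Control library 1 itself helps to set. None of the explanations is therefore excluded and each may apply.

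Clock genes were compared between ASD12h and ASD24h, which ended at clock hours 20 and 8. Over 8 genes the median log2 difference, signed by the daily phase expected for those hours, was 0.59, above the 0.5 set for it, with 8 of 8 in that direction and 0.58 without Control library 1. Time of day at collection is consistent with this value. Arntl differed most (log2 -1.96, edgeR unadjusted p = 0.00183, adjusted p = 0.303), and none of the 8 passed with all libraries, while Arntl passed without Control library 1 (adjusted p = 0.0215). Duration and hour change together, so an effect of duration on clock genes stays open and was not tested.

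Other splits of the libraries were counted for each number of genes called. Any difference among the 4 groups gave 2130 genes in the real split and at most 1191 in the others, and 1 of 100 splits (the real one) reached it. That is the smallest share that 100 splits can give, so chance is unlikely but not excluded. For the mean of the ASD groups the real count was 3436 and the highest other 28, with 1 of 100, so chance is unlikely there as well. For ASD6h, ASD12h and ASD24h against Control 1 of 10 splits reached the real count each, and 10 splits are too few for a share under 0.05. The real counts were 601, 2016 and 3072 and the highest others 3, 160 and 1579, the last with Control library 1 beside ASD24h libraries 2 and 3.

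Scaled to the endothelial identity genes, lists kept medians that differed from 0 to varying degrees. At 6, 12 and 24 h, with the values without Control library 1 in brackets, they were 0.16, -0.02 and -0.02 (0.04, -0.16 and -0.06) for barrier transporters, -0.03, -0.10 and 0.13 (-0.04, -0.14 and 0.07) for basement membrane genes and -0.10, -0.27 and -0.04 (-0.17, -0.46 and -0.14) for capillary genes. Of the 12 capillary genes 2 were lower on that scale at 12 h, and 4 without Control library 1. The medians were 0.48, 0.34 and 0.39 (0.51, 0.34 and 0.56) for junctions, 0.56, 0.54 and 0.51 (0.66, 0.87 and 0.63) for caveolae, 0.52, 0.54 and 0.85 (0.53, 0.63 and 0.46) for vascular tone, 0.28, 0.32 and 0.72 (0.44, 0.67 and 0.97) for Notch, 0.22, 0.66 and 0.77 (0.15, 0.89 and 0.63) for arterial and 0.05, 0.59 and 0.44 (0.35, 0.50 and 0.43) for venous genes. Several of these moved by more than 1.5 times without Control library 1, and no order among the lists is drawn from them. Lower on that scale were Eln (-1.12) and Aoc3 (-1.49) at 6 h, Tfrc (-1.19), Hmcn1 (-1.48) and Adamtsl2 (-1.65) at 12 h and Hmcn1 (-1.12) and Tspan4 (-1.12) at 24 h.

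Some lists had a median, a mean and a camera direction that differ in sign, and none of these was called. At 6 h they were NRF2 genes (median -0.12, mean -0.04, camera up), DNA repair (-0.05, 0.09, up) and interferon genes (0.05, 0.09, down). At 12 h they were fibroblast genes (-0.16, 0.01, up), heat shock genes (-0.08, -0.06, up) and glycolysis genes (0.02, -0.06, up), and at 24 h cholesterol genes (0.03, -0.03, up). Unfolded protein response genes were lower as a list at 6 h (camera adjusted p = 0.0194, a call that ended without Control library 2 or 3 or ASD6h library 1, at 0.0831, 0.0602 and 0.189) and 12 h (camera adjusted p = 0.0131), while its member Ddit3 rose at 6 h (log2 1.09), 12 h (1.18) and 24 h (1.14). Scaled to the endothelial identity genes, where most genes turned higher by construction, this list was not lower. Its medians were 0.93 at 6 h and 0.65 at 12 h, with 13 and 4 members higher and 0 lower.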
